A study of Inocutis levis with 6 samples.

How the data were processed

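Total RNA of the wood-decay fungus Inocutis levis (wild type) was measured by RNA sequencing at day 10 in 3 control samples without Triton X-100, a non-ionic detergent, and in 3 samples given 15 ml of it. Per the labels' protocols, libraries were made with a VAHTS Universal kit and read as 150 bp pairs on an Illumina NovaSeq 6000. Trimmomatic is named in the submitters' processing notes, with no version. The assembler, aligner and quantifier are not given in the sources used here. The unigene identifiers have the form that the assembler Trinity writes. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

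The deposited table of estimated counts holds 12759 unigenes, and between 97.3% and 99% of its values per library are not whole numbers. Counts were therefore rounded to whole numbers before any count test. The deposited FPKM values equal the count divided by unigene length and by 1 constant per library, within 4.9e-05% for unigenes with more than 100 counts. That constant is 10.4% to 11.6% below the library's total count. The deposited sequences carry no gene names, and the files do not pair identifiers with names. No reference genome was used here, so positions are given on the unigenes.

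Unigenes were placed in 30 gene lists by 76 protein motifs fixed before the data were examined. A unigene joined a list when the longest reading frame over its 6 frames, of at least 60 residues, held a motif. The same search was made in 20 shuffles of each frame's residues to count chance matches. Beyond the lists whose chance matches are given in the results, the highest mean was 8.2 against 33 matches, for alcohol and aldehyde dehydrogenases. It was 5.55 against 40 for ABC transporters, 5.6 against 44 for sugar transporters and 5.45 against 36 for peptidases. It was 4.95 against 30 for plant cell wall hydrolases and 1.25 against 7 for glycolysis. Such lists can hold unrelated unigenes. The lists were laccases, other multicopper oxidases, haem peroxidases, tyrosinases, GMC oxidoreductases, cytochrome P450, short-chain dehydrogenases, alcohol and aldehyde dehydrogenases, ABC transporters, sugar transporters, P-type ATPases, mitochondrial carriers, chaperones, antioxidant enzymes, plant cell wall hydrolases, fungal cell wall enzymes, hydrophobins, ubiquitin and proteasome, peptidases, lipases and lipid desaturases, fatty acid oxidation and glyoxylate cycle, glycolysis, polyketide and fatty acid synthases, adenylate-forming enzymes, zinc cluster transcription factors, protein kinases, histones, ribosomal proteins, the mitochondrial genome and viral RNA polymerases. Ribosomal RNA unigenes were those with a conserved fungal 18S or 28S primer site, at most 1 mismatch allowed. A further 4 unigenes matched 1 bacterial 16S site each and were not counted as ribosomal RNA. A further 7 motif lists, searched in any frame of at least 40 residues, were chosen after the values and the sequences had been seen, with chance matches from 1 shuffle only, and the closing part gives the result of each, those that failed included. Motif patterns were written from general knowledge of the families and give a family, not a gene name.

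The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, robust fit, two-sided) with TMM scaling, the tool's own expression filter and Benjamini-Hochberg adjustment. A unigene was called at an adjusted p below 0.05, and calls were counted again at an absolute log2 fold change of at least 1. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM values use the TMM-scaled totals. Lists with at least 3 tested members were compared with all other unigenes by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. The list tests were repeated with an estimated correlation, and fry was run as a test of each list by itself. Single values per library were compared by an exact two-sided permutation test, whose smallest possible p with 3 against 3 is 0.1.

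The steps were tested on simulated data. In counts drawn for the real unigenes with 200 of them changed (Triton against control, 11467 unigenes tested), the fit recovered 7.14% of unigenes changed 2-fold and 52.1% of those changed 4-fold. Of its 58 calls, 1 was false. A planted list of 40 unigenes, all raised 2-fold, had an adjusted p of 2.71e-26 by camera, and 0 of 29 unchanged lists were called. Each unigene was drawn independently, so this cannot show how camera treats lists with correlated members or mixed directions. With only 200 planted changes and 58 calls, the Benjamini-Hochberg threshold was stricter there than in the real fit, which called 2854 unigenes. The recoveries depend on that as well as on spread and depth, so they do not carry over to the real fit.

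Named unigenes followed a rule fixed before the data were examined. It took every tested laccase up to 10. From each other list it took, in each direction, the unigene with the largest absolute log2 fold change among called unigenes with a mean CPM of at least 10 and no overlap of the groups, keeping the 24 with the highest mean CPM out of 41. Among unigenes in no list it took the 2 largest rises and the 2 largest falls by the same conditions. Other members named as examples of a list were chosen after their values were seen.

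Alternatives set in advance were DESeq2 size factors, library size alone, no filter beyond a total count of 1, a CPM of at least 1 in 3 libraries, each library left out, the replicate number as a block, DESeq2's Wald test (DESeq2 1.42.0), and limma on log2(FPKM + 1) or log2(FPKM + 0.1) for FPKM of at least 1 in 3 libraries or with no such filter. Lists were also rebuilt from any frame of at least 100 residues and from frames of at least 150 residues. Alternatives chosen after seeing the data left out the ribosomal RNA unigenes, summed counts over clusters of near-identical unigenes, removed each library's trend with GC content and length (lowess span 0.3), and left out a pair of libraries. Near-identical unigenes were found with blastn 2.17.0: 5919 unigenes (46.4%) shared at least 200 nt at 95% identity or more with another, and 4817 of them fell into 2207 clusters that shared at least 50% of the shorter unigene. Reads of such unigenes can be split between copies by the authors' counting, and the use of strand is not given in the sources used here.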

Results

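Expression in Inocutis levis, a wood-decay fungus, was compared at day 10 between 3 control samples without Triton X-100 and 3 samples given 15 ml of this detergent. The deposited values were estimated counts per assembled unigene. Total counts were 20699519, 19046650 and 23122066 in control replicates 1 to 3 and 22799832, 19796044 and 20188896 in Triton replicates 1 to 3. Between 12407 and 12628 of the 12759 unigenes had at least 1 count in a library. The 2 groups lay apart: Pearson's r of log2 CPM across unigenes was 0.94 to 0.97 within the controls, 0.96 to 0.97 within the Triton samples and 0.85 to 0.89 between the groups, where unigenes are not independent replicates. The first principal component held 64.2% of the variance and separated the groups, and the second held 15.6%, with control replicate 3 at -57.8 and the other controls at 35.6 and 27.1, and Triton replicate 1 at -30.0 and the other Triton samples at 11.3 and 13.8. As a check for a library deposited more than once, the chi-square per degree of freedom between libraries of a group was 122.4 to 234.3, and each library was counted as a sample of its own.

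The series concerns laccase production, and laccases are multicopper oxidases that oxidise phenols and take part in lignin breakdown. With Triton, 1 of the 7 laccase unigenes rose and the other 6 were not called. TRINITY_DN5958_c0_g1_i2_2 had 7.84 ± 0.543 CPM in the controls and 291.7 ± 113 CPM with Triton (SD, n = 3), a log2 fold change of 5.22 (SE 0.38, edgeR quasi-likelihood test, adjusted p = 0.000295), and every Triton library lay above every control library. Its share of all laccase CPM was 2.46% ± 0.358 in the controls and 42.9% ± 9.14 with Triton (SD, n = 3, exact permutation p = 0.1, the smallest this design allows). Summed laccase CPM was 324.6 ± 63.7 in the controls and 670.9 ± 210 with Triton (SD, n = 3, exact permutation p = 0.1), a ratio of 2.07.

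The motifs of both laccase copper regions lie in a frame of 536 residues at nucleotides 1657 to 3264 of the 3542 nt TRINITY_DN5958_c0_g1_i2_2. Its counts are for the whole unigene, so reads from outside that frame can be among them. This unigene shares 932 nt at 99.79% identity with TRINITY_DN6056_c0_g1_i3_1, so some of its reads can be counted there. The laccase with the most control CPM, TRINITY_DN642_c0_g1_i11_1, had 142.3 ± 33.1 CPM in the controls and 243.8 ± 107 with Triton (SD, n = 3, edgeR adjusted p = 0.133). TRINITY_DN3580_c0_g1_i22_1 and TRINITY_DN5232_c0_g1_i4_1 had log2 fold changes of 0.36 and 0.58 (edgeR adjusted p = 0.318 and 0.375). TRINITY_DN5370_c0_g1_i11_2 and TRINITY_DN1121_c0_g1_i10_1, which share 3262 nt at 99.88% identity and so have uncertain separate values, had log2 fold changes of -0.58 and -0.52 (edgeR adjusted p = 0.0909 and 0.169). TRINITY_DN76_c0_g1_i17_1 had a log2 fold change of -2.19 (SE 0.77, edgeR adjusted p = 0.069), with 45.2 CPM in control replicate 3 against 7.22 and 7.71 in the other controls. Without control replicate 3 its log2 fold change was -0.76 (edgeR adjusted p = 0.294), without control replicate 2 its adjusted p was 0.0495, and DESeq2's Wald test gave 0.009, so that either of the last settings called 2 laccases. It shares 2349 nt at 99.15% identity with TRINITY_DN4357_c0_g1_i28_2, which is in the list of other multicopper oxidases, so both values are uncertain. Adjusted over the list alone, 1 laccase rose and 0 fell. The 2 unigenes of that other list, 1 of them this near-identical partner, were not called (median log2 fold change -0.37, 0 called adjusted over the list alone).

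**Figure D1:**
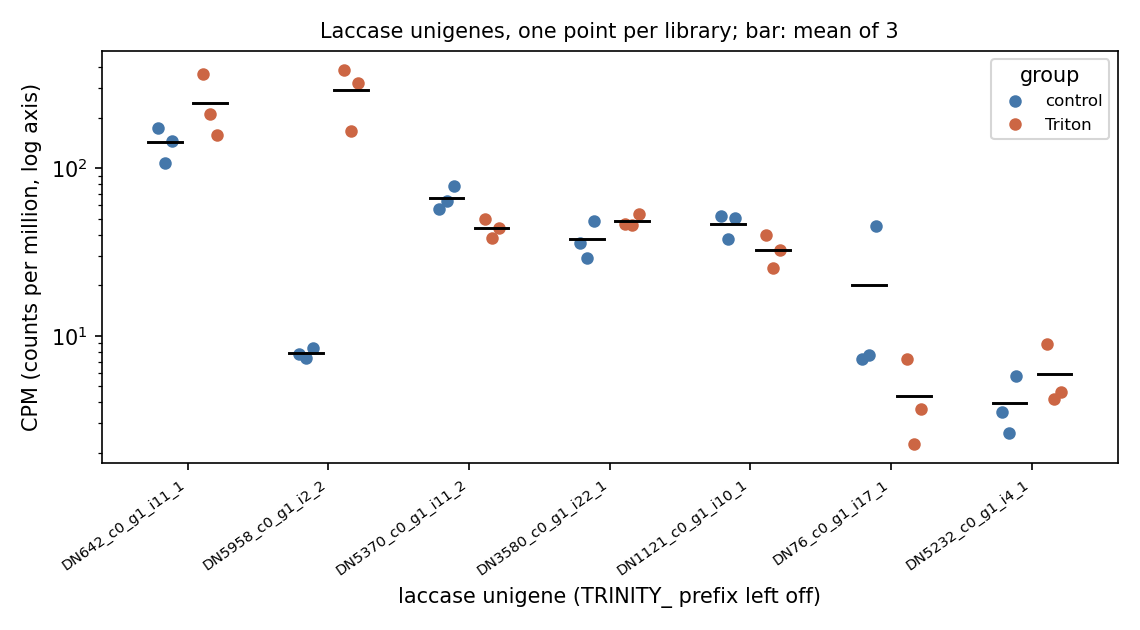
CPM (log axis) of the 7 laccase unigenes in each of the 3 control and 3 Triton libraries, 1 point per library, with a bar at the mean of each group. TRINITY_DN5958_c0_g1_i2_2 moves from a mean of 7.84 to 291.7 CPM with no overlap of the groups, and the other 6 unigenes were not called.

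Across all 11629 tested unigenes, 2854 (24.5%) differed, of which 1489 were higher and 1365 lower with Triton (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Of these, 1284 rose and 1227 fell by at least 1 on the log2 scale. The groups did not overlap for 43.2% of tested unigenes, where chance gives 10%. The count fell to 1829 without control replicate 2, to 1516 without Triton replicate 2 and to 1569 without Triton replicate 3, fits that have fewer libraries. The rises numbered 987, 936, 885 and 954 without control replicates 1 and 2 and Triton replicates 2 and 3, and the falls 893, 631 and 615 without the last 3 of these in turn. Without control replicate 1, which holds a few unigenes almost absent elsewhere, and Triton replicate 2, which has the highest share of ribosomal RNA, 888 unigenes were called, an alternative chosen after seeing the data. The 2 unigenes with fungal ribosomal RNA sites took 0.201% ± 0.0187 of counts in the controls and 0.873% ± 0.659 with Triton (SD, n = 3, exact permutation p = 0.1), with 1.62% in Triton replicate 2.

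Of 38 tested transporters of the ABC family, which pump lipids, drugs and other compounds across membranes, 10 rose with Triton, 0 fell and 28 were not called. The list's median log2 fold change was 0.43, with a camera adjusted p of 0.0132 that was lost with an estimated correlation (adjusted p = 0.451). Adjusted over the list alone, 11 rose and 0 fell, and without control replicate 1, 8 rose and 1 fell. TRINITY_DN1030_c0_g1_i19_1 changed most, from 134.2 ± 64.2 to 4804 ± 1713 CPM (SD, n = 3), a log2 fold change of 5.16 (SE 0.48, edgeR adjusted p = 0.000502). TRINITY_DN642_c0_g1_i44_2, TRINITY_DN946_c0_g1_i26_1 and TRINITY_DN464_c0_g1_i25_1 rose by 2.79, 2.68 and 2.63 on the log2 scale, the last by 2.01 without Triton replicate 1. The 10 called unigenes include 2 near-identical pairs, TRINITY_DN642_c0_g1_i44_2 with TRINITY_DN601_c0_g1_i11_1 (4851 nt shared at 99.61%) and TRINITY_DN2547_c0_g1_i2_2 with TRINITY_DN3033_c0_g1_i2_1 (2443 nt at 99.75%), whose separate values are uncertain. With counts summed over near-identical unigenes, 8 of 35 clusters rose and 0 fell. TRINITY_DN1030_c0_g1_i19_1 shares 649 nt at 99.69% identity with another unigene on the opposite strand.

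Of 12 tested chaperones, which help proteins fold, 4 rose, 0 fell and 8 were not called, and all 12 had a positive log2 fold change in this fit. The list's camera adjusted p of 0.0219 was lost with an estimated correlation (adjusted p = 0.451) and without control replicate 3 (adjusted p = 0.128). Adjusted over the list alone, 6 rose and 0 fell. Only 2 rose without control replicates 1, 2 or 3 or Triton replicate 2, 3 without Triton replicate 3, and 6 without Triton replicate 1. The HSP70 unigene TRINITY_DN1497_c0_g1_i1_1 went from 187.5 ± 19.1 to 949.7 ± 111 CPM (SD, n = 3), a log2 fold change of 2.34 (SE 0.25, edgeR adjusted p = 0.000811). TRINITY_DN3195_c0_g1_i20_2, with a DnaJ domain found in HSP70 partners, rose by 2.20.

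P-type ATPases, ion and lipid pumps of membranes, counted 5 rises and 0 falls among 15 tested (5 and 0 adjusted over the list alone). The rises numbered 2 without control replicates 1, 2 or 3 and 3 without Triton replicate 3, and 1 fell without control replicate 3. TRINITY_DN1708_c0_g1_i1_1 rose from 61.8 ± 8.20 to 337.6 ± 55.9 CPM (SD, n = 3, log2 fold change 2.45, SE 0.25, edgeR adjusted p = 0.000695). The list was not called by camera (adjusted p = 0.145). Enzymes of fatty acid oxidation and the glyoxylate cycle counted 4 rises and 1 fall among 9 tested (4 and 1 adjusted over the list alone, camera adjusted p = 0.0955). The thiolase-motif unigene TRINITY_DN7709_c0_g1_i1_2 rose from 61.8 ± 7.53 to 597.3 ± 112 CPM (SD, n = 3, log2 fold change 3.27, SE 0.27). The thiolase family holds the enzyme of the last step of fatty acid oxidation, but the motif does not show that this unigene has that role. The acyl-CoA dehydrogenases TRINITY_DN1882_c0_g1_i3_2 and TRINITY_DN5527_c0_g1_i2_1 rose by 3.22 and 1.68 on the log2 scale. TRINITY_DN1582_c0_g1_i1_1, with the isocitrate lyase motif of the glyoxylate cycle, fell by 2.11 on the log2 scale, from 5176 ± 1201 to 1200 ± 447 CPM (SD, n = 3).

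Oxidative enzymes moved in both directions. Cytochromes P450, haem enzymes that oxidise many small molecules, had 13 rises and 13 falls among 56 tested (16 and 15 adjusted over the list alone, camera adjusted p = 0.96). TRINITY_DN6511_c0_g1_i1_2 rose by 6.05 on the log2 scale, from 3.21 ± 3.18 to 212.1 ± 46.7 CPM, and TRINITY_DN4977_c0_g1_i2_2 fell by 5.73, from 353.0 ± 302 to 6.64 ± 3.50 CPM (SD, n = 3). Without control replicate 2 these log2 fold changes were 7.26 and -5.02. With 1 library left out, the rises of cytochromes P450 ranged from 10 to 14 and their falls from 9 to 15. Short-chain dehydrogenases had 9 rises and 5 falls among 22 tested (11 and 5 adjusted over the list alone, camera adjusted p = 0.222), with TRINITY_DN1065_c0_g1_i17_1 at 44.2 ± 6.92 CPM in controls and 1046 ± 519 with Triton (SD, n = 3, log2 fold change 4.56, SE 0.42). Their rises numbered 4 without Triton replicate 2, and their falls 3 without control replicate 1 and 2 without control replicates 2 or 3 or Triton replicates 2 or 3. Alcohol and aldehyde dehydrogenases had 3 rises and 7 falls among 33 (3 and 8 adjusted over the list alone, camera adjusted p = 0.222), with 5 rises without control replicate 3 and 4 falls without control replicate 2 or Triton replicate 3. GMC oxidoreductases, flavin enzymes of the glucose oxidase family, had 2 rises and 1 fall among 7 (2 and 1 adjusted over the list alone, camera adjusted p = 0.938): TRINITY_DN559_c0_g1_i45_1 rose by 3.70 and TRINITY_DN48_c0_g1_i2_1 fell by 1.29 on the log2 scale. Only 1 rose without control replicates 1 or 2 or Triton replicates 1, 2 or 3, and 2 fell without control replicate 3. Among 10 antioxidant enzymes 3 rose and 2 fell (5 and 4 adjusted over the list alone, camera adjusted p = 0.537). With 1 library left out, their rises ranged from 2 to 4 and their falls from 2 to 3. The thioredoxin-motif unigene TRINITY_DN3421_c0_g1_i2_1 rose from 97.4 ± 10.9 to 822.2 ± 174 CPM. The superoxide dismutase TRINITY_DN3665_c0_g1_i1_1 fell from 3483 ± 312 to 542.5 ± 70.4 CPM (SD, n = 3), and the catalase TRINITY_DN5111_c0_g2_i1_1 fell by 2.32 on the log2 scale. The haem peroxidase motifs matched 10 unigenes where shuffled frames gave 9.45, so the list does not identify peroxidases; 2 rose and 3 fell (2 and 3 adjusted over the list alone), with TRINITY_DN1810_c0_g1_i1_1 up by 4.18 on the log2 scale (4.79 without control replicate 3). Only 1 fell without control replicates 1, 2 or 3 or Triton replicates 2 or 3.

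Of 7 hydrophobins, small proteins that coat the surface of hyphae, 3 fell and 1 rose (4 and 1 adjusted over the list alone, camera adjusted p = 0.222). TRINITY_DN221_c0_g1_i1_2 fell by 5.05 on the log2 scale, from 176.1 ± 111 to 5.32 ± 2.14 CPM (SD, n = 3), and TRINITY_DN6055_c0_g1_i1_1 fell by 1.44. The rise was not called without control replicates 1 or 2 or Triton replicate 2 (edgeR adjusted p = 0.0823, 0.0698 and 0.106), and 2 rose without control replicate 3. The falls numbered 4 without control replicate 2 and 2 without control replicate 1 or Triton replicates 1, 2 or 3. With counts summed over near-identical unigenes, 0 hydrophobins rose and 3 fell. Of 4 tyrosinases, copper enzymes of melanin synthesis, 2 fell and 0 rose (2 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.222): TRINITY_DN6674_c0_g1_i1_1 fell by 3.75 (SE 0.31) and TRINITY_DN9154_c0_g1_i1_2 by 4.05 (SE 1.18) on the log2 scale. TRINITY_DN9154_c0_g1_i1_2 had 268.1 CPM in control replicate 2 against 19.1 and 7.66 in the other controls and 7.09, 4.53 and 6.19 with Triton. Without control replicate 2 its log2 fold change was -1.17 (edgeR adjusted p = 0.123), and it was not called without Triton replicates 1, 2 or 3 (edgeR adjusted p = 0.101, 0.159 and 0.139). Plant cell wall hydrolases had 2 rises and 5 falls among 30 (2 and 5 adjusted over the list alone, camera adjusted p = 0.915), with a family 5 glycosyl hydrolase, TRINITY_DN1409_c0_g1_i1_2, down by 2.44 on the log2 scale. Their rises numbered 1 without control replicate 1 and 0 without control replicate 2 or Triton replicate 3. Their falls numbered 2 without control replicate 1 or Triton replicate 1, 1 without Triton replicate 2, and 3 without control replicate 2 or Triton replicate 3, and summed over near-identical unigenes 1 rose and 5 fell. Fungal cell wall enzymes had 1 rise and 3 falls among 29 (1 and 2 adjusted over the list alone, camera adjusted p = 0.484), with 2 rises without control replicate 3 and 3 without Triton replicate 1. Of these enzymes 1 fell without control replicates 1 or 2 or Triton replicate 1, and 0 without Triton replicates 2 or 3.

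In glycolysis 1 of 7 tested unigenes fell and 0 rose (0 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.0955). This was TRINITY_DN8152_c0_g1_i20_2, with the GAPDH motif, from 13060 ± 4267 to 5708 ± 1643 CPM (SD, n = 3, log2 fold change -1.19, edgeR adjusted p = 0.0433). It was not called without control replicates 1, 2 or 3 (edgeR adjusted p = 0.0698, 0.0663 and 0.112) or Triton replicates 2 or 3 (0.131 and 0.122), 2 unigenes fell without Triton replicate 1, and it shares 1459 nt at 99.59% identity with another unigene. The polyubiquitin-motif unigene TRINITY_DN114_c0_g1_i24_1, which shares 1802 nt at 99.78% identity with another unigene, rose by 1.73 and the ubiquitin-conjugating enzyme TRINITY_DN2729_c0_g1_i2_1 fell by 1.31 on the log2 scale, the calls of 13 tested in that list (1 and 1 adjusted over the list alone, camera adjusted p = 0.26). The fall was not called without Triton replicate 2 or 3 (edgeR adjusted p = 0.0741 and 0.0744), and 2 rose without Triton replicate 1. Peptidases had 4 rises and 5 falls among 35 (5 and 5 adjusted over the list alone, camera adjusted p = 0.465), with TRINITY_DN1726_c0_g1_i2_1 up by 0.94 on the log2 scale. That rise was not called without control replicates 1, 2 or 3 (edgeR adjusted p = 0.0975, 0.0626 and 0.0509) or Triton replicates 1 or 3 (0.059 and 0.0797). Peptidase rises numbered 2 without control replicates 1 or 2 or Triton replicate 3, and falls 3 without control replicates 1 or 2 and 2 without Triton replicates 2 or 3.

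Among regulators, 8 of 56 zinc cluster transcription factors rose and 10 fell (10 and 10 adjusted over the list alone, camera adjusted p = 0.465): TRINITY_DN7933_c0_g1_i2_2 rose by 2.69 and TRINITY_DN6278_c0_g1_i2_2 fell by 5.14 on the log2 scale. Their falls numbered 6 without control replicate 1, 5 without Triton replicate 2 and 3 without Triton replicate 3. Protein kinases had 11 rises and 5 falls among 103 (10 and 5 adjusted over the list alone, camera adjusted p = 0.782), but 20 and 9 without control replicate 3, 7 and 3 without Triton replicate 3, and 9 and 3 without Triton replicate 2. Of 4 histones 2 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.0955), both with the H2A motif; the histone motifs matched 5 unigenes where shuffled frames gave 2.1. The 4 ribosomal proteins were not called (camera adjusted p = 0.484, 0 adjusted over the list alone). Sugar transporters had 3 rises and 6 falls among 44 (3 and 4 adjusted over the list alone, camera adjusted p = 0.782), with TRINITY_DN350_c0_g1_i18_2 up by 2.83 on the log2 scale. These had 5 rises without control replicate 3 or Triton replicate 1, and 3 falls without Triton replicates 2 or 3. Mitochondrial carriers, whose 45 matches stood against 20.25 by chance, had 9 rises and 3 falls among 43 (10 and 3 adjusted over the list alone, camera adjusted p = 0.0955). The carriers had 5 rises without control replicate 2 and 4 without Triton replicate 2, with 1 fall without control replicate 1 or Triton replicate 1 and 0 without control replicate 2 or Triton replicates 2 or 3. Adenylate-forming enzymes had 5 rises and 1 fall among 16 (5 and 2 adjusted over the list alone, camera adjusted p = 0.26), with TRINITY_DN1808_c0_g1_i1_2 up by 3.44, and 2 falls without control replicate 1. Lipases and lipid desaturases had 4 rises and 2 falls among 22 (9 and 2 adjusted over the list alone, camera adjusted p = 0.211), with TRINITY_DN3416_c0_g1_i15_2 down by 1.75, 2 rises without control replicate 2 or Triton replicates 2 or 3, and 1 fall whichever library was left out. None of 4 polyketide and fatty acid synthases was called by edgeR (camera adjusted p = 0.65, 0 adjusted over the list alone). Of 2 tested unigenes with mitochondrial genome motifs 1 rose and 0 fell (1 rose and 1 fell adjusted over the list alone). The rise was TRINITY_DN8941_c0_g1_i1_1, at low values in both groups, from 0.909 ± 0.529 to 4.84 ± 2.62 CPM (SD, n = 3). The fall was TRINITY_DN8399_c0_g1_i1_2, with 19.3 CPM in control replicate 1 against 1.29 and 0.29 in the other controls (log2 fold change -4.29, edgeR adjusted p = 0.0555 over all unigenes). Its GC content is 40.1%, and control replicate 1 is the library where a trace of vertebrate RNA is considered in the closing part. Whether this unigene is the fungus's own is therefore uncertain. The list's rises and falls were 0 and 0 without control replicate 1 or Triton replicate 2, 0 rises and 1 fall without control replicate 2, and 1 rise and 2 falls without control replicate 3. The fits without control replicates 2 or 3 or Triton replicates 1 or 2 tested 3 unigenes of the list. The added unigene, TRINITY_DN8487_c0_g1_i1_2, carries a vertebrate-form motif and had 236 counts in control replicate 1, where nearly all of its counts lie. Its source is uncertain as well. In addition, 0 unigenes matched the viral polymerase motifs.

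Summing counts over near-identical unigenes also changed the rises and falls of other lists. They became 2 and 2 for haem peroxidases, 14 and 12 for cytochromes P450, 7 and 5 for short-chain dehydrogenases, 4 and 8 for alcohol and aldehyde dehydrogenases, and 3 and 5 for sugar transporters. They were 10 and 3 for mitochondrial carriers, 4 and 2 for antioxidant enzymes, 1 and 4 for fungal cell wall enzymes, and 5 and 3 for lipases and lipid desaturases. For adenylate-forming enzymes they were 4 and 1, for zinc cluster transcription factors 8 and 9, and for protein kinases 10 and 6.

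By camera 2 of 27 lists were called with the preset correlation and 0 with an estimated correlation. Fry, which tests each list by itself, called 13 lists in 1 direction and 25 in either direction. It does not compare a list with other unigenes, and 24.5% of all tested unigenes were called. Its counts therefore do not show that these lists changed more than unigenes at large.

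**Figure D2:**
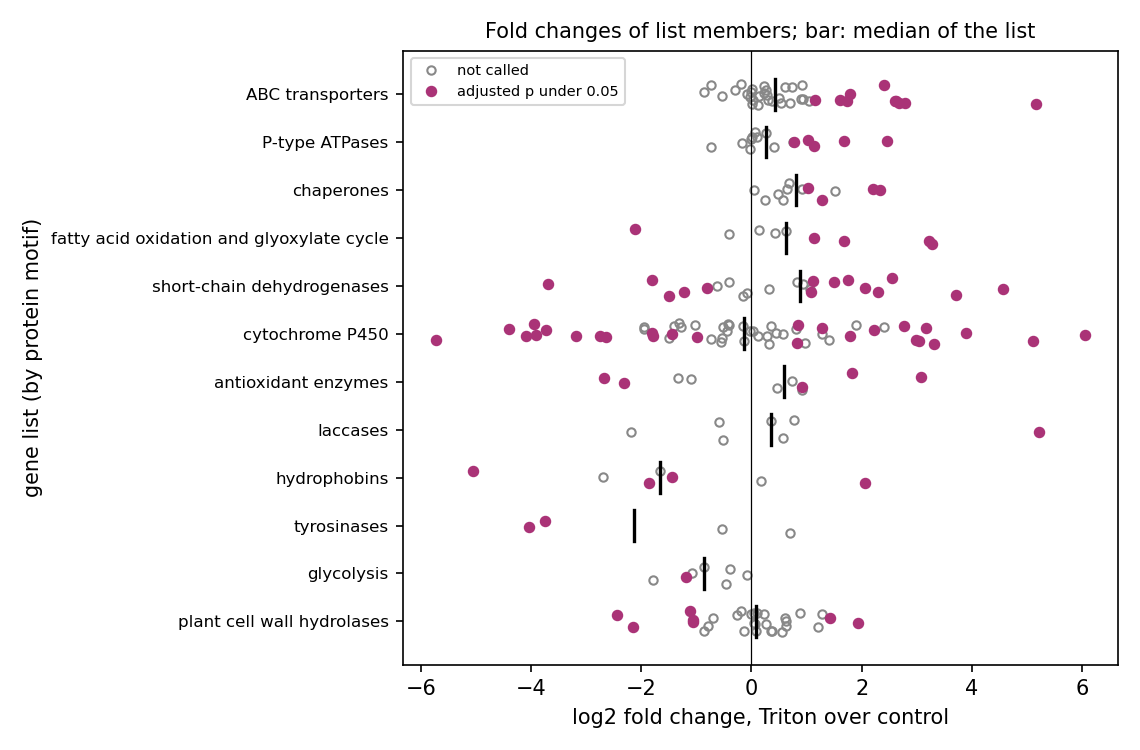
Log2 fold change (Triton over control) of each tested unigene in 12 of the gene lists, with filled points for unigenes with an adjusted p under 0.05, open points for the rest and a bar at the list's median. The called ABC transporters, 10 of 38 tested, and chaperones, 4 of 12, all lie to the right of 0, and the cytochromes P450 spread to both sides with 13 rises and 13 falls.

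Among unigenes in no list, the largest rises by the rule were TRINITY_DN1102_c0_g1_i3_1 and TRINITY_DN302_c0_g1_i14_1. The former had 0 counts in the controls and 33.8 ± 8.09 CPM with Triton (SD, n = 3), at least 237-fold higher against a floor of 3 counts per control library. The latter had 0.268 ± 0.306 CPM in the controls and 406.8 ± 289 with Triton (SD, n = 3, log2 fold change 10.59, edgeR adjusted p = 0.000436). It shares 2706 nt at 99.78% identity with TRINITY_DN3435_c1_g1_i2_2, so reads can be split between them, and its log2 fold change ranged from 6.90 to 12.04 over the alternatives, with 12.04 without control replicate 2 and 9.89 without Triton replicate 1. The largest falls were TRINITY_DN6862_c0_g1_i1_1 and TRINITY_DN3036_c0_g1_i1_2, by 10.53 and 9.15 on the log2 scale (SE 1.95 and 1.24). The log2 fold change of the former was -7.15 without control replicate 1, -12.03 without Triton replicate 2 and -9.94 without Triton replicate 3, and that of the latter -8.47 without control replicate 2 and -10.33 without Triton replicate 2. TRINITY_DN6862_c0_g1_i1_1 had 631.7 CPM in control replicate 1 against 32.7 and 10.3 in the other controls, and TRINITY_DN3036_c0_g1_i1_2 had 2131, 3330 and 236.8 CPM in the controls and 3.36 ± 3.28 with Triton (SD, n = 3).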

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

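Alternatives that left out ribosomal RNA unigenes, summed near-identical unigenes, removed the GC and length trend, or left out a pair of libraries were chosen after seeing the data. Of the 2854 called unigenes, 98.4% were called in the same direction with DESeq2 size factors, 95.1% with library size only, 94.9% with no filter and 87.8% by limma on log2(FPKM + 1), but 61.1% with the replicate block, 51.5% to 78% with 1 library left out and 30% with the pair left out. The median log2 fold change moved by at most 0.0383 under any alternative. TMM and DESeq2 scaling hold this median small by design, so it says little about the calls. The count of called unigenes ranged from 1516 to 2679 with 1 library left out, was 1763 with the replicate block, and was 888 without control replicate 1 and Triton replicate 2 together, where fewer samples enter. The replicate numbers gave no sign of pairing the samples: deviations of same-numbered libraries correlated at -0.2, 0.024 and -0.2, and none correlated best with its own number. So few libraries cannot exclude a pairing. With counts summed over clusters, 72 of the 2854 unigenes had the opposite sign, and TRINITY_DN76_c0_g1_i17_1 with its near-identical partner had a log2 fold change of -1.01 and was not called by edgeR. The count of called laccases was 2 by DESeq2's Wald test and between 1 and 2 with 1 library left out. The count of called lists was 0 with an estimated correlation and ranged from 1 to 3 with 1 library left out, where chaperones had adjusted p values from 0.00297 to 0.128. Both called lists had a camera adjusted p of 0.451 with an estimated correlation. The estimates were 0.0157 for ABC transporters and 0.0374 for chaperones, against the preset 0.01. In that mode camera uses only the residual degrees of freedom of these few libraries and has less power. The loss therefore does not show that correlated members carried the signal. The mean r within groups exceeded that between groups by 0.647 over the 1000 most abundant unigenes and by 0.106 on log2(FPKM + 1), and the cause was not tested. Pearson's r depends on the spread of levels among the unigenes used, so these gaps cannot be compared with each other. The 29 named unigenes that were called gave 551 values under the alternatives, of which 529 were still called, 22 were not and 0 changed direction. Nearly all of them were picked from these data for a call, a large fold change and no overlap of the groups. That choice largely fixed their direction, so these counts do not describe the called unigenes at large. Totals of 19046650 to 23122066 counts limit what can be seen of unigenes with few counts.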

Other observations

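The tests of shared reads, of scaling, of foreign mitochondrial RNA and of other mitochondrial transcripts, and all 7 motif lists in the next paragraph, were chosen after the result was seen.

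Several of the most abundant changed unigenes were in no list fixed in advance, and they went both ways. TRINITY_DN5322_c0_g1_i7_1 fell from 24201 ± 6164 to 4035 ± 657 CPM (SD, n = 3, edgeR adjusted p = 0.00199). TRINITY_DN251_c0_g1_i8_1 fell from 7854 ± 1291 to 3423 ± 726 CPM (SD, n = 3, edgeR adjusted p = 0.0238). TRINITY_DN1848_c0_g1_i4_2, matched only by the dioxygenase motif weighed below, fell from 2816 ± 353 to 85.1 ± 15.0 CPM (SD, n = 3, edgeR adjusted p = 0.000192). The aldo-keto reductase loop, from a family of carbonyl-reducing enzymes, matched 5 unigenes and 0 in 1 shuffle of the frames. Of 4 tested, 2 rose and 0 fell: TRINITY_DN2167_c0_g1_i5_1 by 1.63 on the log2 scale (not called without control replicate 1, edgeR adjusted p = 0.0578), and TRINITY_DN5768_c0_g1_i74_2 from 53.2 ± 17.1 to 18677 ± 6086 CPM (SD, n = 3), though 1111 nt of the latter also occur in another unigene on the opposite strand. TRINITY_DN5032_c0_g1_i2_2 and TRINITY_DN7357_c0_g1_i12_1 had log2 fold changes of -0.69 and -0.34 (edgeR adjusted p = 0.158 and 0.694). The old yellow enzyme loop, from flavin enzymes that reduce unsaturated carbonyls, matched 5 unigenes and 0 in 1 shuffle. Of these 4 rose and 0 fell, but they hold 2 near-identical pairs, and with counts summed over copies 2 of 3 clusters rose and 0 fell. TRINITY_DN2046_c0_g1_i2_2 and TRINITY_DN1935_c0_g1_i3_1, nearly identical copies, rose by 5.54 and 5.23 on the log2 scale (6.42 and 6.44 without control replicate 2), and TRINITY_DN1798_c0_g1_i2_1 and TRINITY_DN691_c0_g1_i15_1 by 1.31 and 1.29, calls that were each lost when any of 4 libraries was left out (edgeR adjusted p from 0.055 to 0.0932). TRINITY_DN5748_c0_g1_i130_2, with which TRINITY_DN691_c0_g1_i15_1 shares 2607 nt at 99.65% identity, had a log2 fold change of 0.17 (edgeR adjusted p = 0.852). Summed, this pair had 0.372 (SE 0.503, edgeR adjusted p = 0.611), so the rise of TRINITY_DN691_c0_g1_i15_1 is not separable from reads split between copies. The HSP90 helix matched TRINITY_DN1917_c0_g1_i2_1 alone, which rose from 1067 ± 182 to 4640 ± 2834 CPM (SD, n = 3). It was not called without control replicates 1, 2 or 3 or Triton replicates 1 or 2 (edgeR adjusted p from 0.0501 to 0.056). The beta-carbonic anhydrase site matched TRINITY_DN75_c0_g1_i1_1 alone, with a log2 fold change of -0.16 (edgeR adjusted p = 0.69). The dioxygenase motif matched 24 unigenes and 25 in 1 shuffle, so it identifies nothing; 3 rose and 6 fell. Fungal mitochondrial motifs matched 0 unigenes and vertebrate-form mitochondrial motifs matched 2.

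The 2854 called unigenes were weighed against chance and sequence bias. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many calls, the real one with 2854, and the highest other split gave 0; so few splits cannot give a share under 0.05. After each library's GC and length trend was removed, 92.5% of the calls held in the same direction, which argues against those trends as the whole cause. The detergent and any unrecorded handling difference between the groups stay open.

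The rise of the laccase unigene TRINITY_DN5958_c0_g1_i2_2 may be a response to the detergent, as a hypothesis. With the counts of its near-identical partner added, the log2 fold change was 5.14 (SE 0.377), which argues against reads moving between copies. Its share of laccase CPM, which no factor per library can change, was 17.4 times higher with Triton (2.46% ± 0.358 against 42.9% ± 9.14, SD, n = 3), which argues against scaling as the whole cause. A handling difference between the groups was not tested.

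A few unigenes had most of their counts in control replicate 1: 6 unigenes had more than 100 counts there and over 20 times those of any other library, with a median GC content of 39.4% against 49.4% for all unigenes. The rule used counts before scaling for depth. By the same rule control replicate 3 had 4 such unigenes, control replicate 2 had 1, Triton replicate 3 had 2 and Triton replicates 1 and 2 had 0, with 2461 counts in control replicate 3 and 13601 in control replicate 1. Of the 13601 counts, 12863 (94.6%) came from TRINITY_DN6862_c0_g1_i1_1, whose GC content is 45.7%. That unigene was not confined to control replicate 1: it had 631.7 CPM there and 32.7 and 10.3 CPM in control replicates 2 and 3. Of the other 5 unigenes, 4 had a GC content of 37.4% to 40% and 1 of 50.8%. The 2 unigenes with vertebrate-form mitochondrial motifs had 359 counts, or 17.3 CPM, there (exact Poisson interval 15.6 to 19.2, counting error only) and at most 0.704 CPM elsewhere, a ratio of 24.7 (14.7 to 46.2). Both are among the 6 unigenes picked for over 20 times the counts of any other library. That choice largely fixed the ratio, so it is no separate support for a foreign source. Their motifs and low GC content leave a trace of vertebrate RNA in that library possible. Neither bears on TRINITY_DN6862_c0_g1_i1_1. A higher level of all mitochondrial transcripts there stays open: the other cox1 unigene, TRINITY_DN8941_c0_g1_i1_1, stood at 0.354 times (0.157 to 0.685) the higher of the other controls, but at 0.54 CPM it lies too near the floor to decide. Beyond this undecided test no biological explanation was tested, and the source of the other unigenes, TRINITY_DN6862_c0_g1_i1_1 among them, stays open.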
